A study of Arabidopsis thaliana with 18 samples.

How the data were processed

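RNA was measured on single-colour oligonucleotide arrays in Arabidopsis thaliana root tips. Per the labels, seedlings were grown for 5 days, moved to medium with or without 1 µM of the peptide TOLS2 for 3 h, and about 80 root tips of 1 cm were pooled per sample. The 18 arrays fall into 6 groups of 3, which the labels call biological replicates: wild type, rlk7-3 and puchi-2, each as control and with TOLS2. Samples were placed in groups by their titles. No pair of arrays held equal values in most rows (0 pairs), so each array counts as 1 replicate.

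The deposited values are log2 expression levels per probe set, made by the authors with RMA (background correction, quantile normalization and summary of probes), per the submitters' processing notes. The software version, the probe set definition and the genome build are not given in the sources used here. The values ran from 0.38 to 13.98 and the array medians from 6.19 to 6.30. They were used as deposited, with no pseudocount and no filter on dim probe sets. RMA brings all arrays to a common distribution, so a change shared by most genes would not be seen, and it shrinks differences of dim probe sets. For arrays, the number of replicates limits the precision.

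The table holds 38408 rows. The annotation table of the platform gave exactly 1 gene for 16722 rows, several genes for 759 and none for 20927 (54.5%). Tests covered the 17481 rows with at least 1 gene, and rows with several genes were counted but never named. Names were updated through Entrez identifiers with a RefSeq gene table of assembly TAIR10.1, which matched 16574 of the 1-gene rows. That table served only for names and for the order of genes along chromosomes. Where a gene had several probe sets, the one with the highest mean over all arrays stands for it. The values of 7132 rows were identical to those of another row, 140 of them among the rows tested, so counts of probe sets include some repeats. No row was named for RLK7, so its transcript could not be followed.

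Changes were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, 6 group means over all 18 arrays, 12 residual degrees of freedom). A probe set is called at an adjusted p under 0.05 (Benjamini-Hochberg over the 17481 probe sets, two-sided). There were 7 comparisons: TOLS2 against control in each genotype, the difference of the TOLS2 response of each mutant from that of wild type (the interaction), and each mutant against wild type among control arrays. Values written with ± are means with SD over 3 arrays, and SE is that of the limma estimate. A mean over the probe sets that rose at least 2-fold in wild type was taken per array and compared within each mutant by an exact two-sided permutation test, whose smallest possible p with 3 against 3 arrays is 0.1. On simulated data with the spread of these arrays and 200 changed probe sets, the wild-type comparison recovered 89 of 100 changes of 1 on the log2 scale and 46 of 100 changes of 0.5, with 11 false calls. The rlk7-3 interaction recovered 68 and 20 of 100, with 3 false calls.

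The groups, tests, alternatives, naming rule and 22 gene lists were fixed before the data were examined. The lists covered immune, calcium and touch, ethylene, jasmonate, auxin response, lateral root, cell cycle, cytokinin, wall loosening, very-long-chain fatty acid and suberin, endodermis, root hair, root cap, xylem, stem cell niche, photosynthesis and shoot, heat, hypoxia, abscisic acid with cold and drought, iron, nitrate, and peptide and receptor genes. Of 340 members written, 14 were dropped because their symbols did not match the annotation, and 46 entries were measured with 1 gene. The ethylene, suberin, endodermis, root cap, hypoxia and nitrate lists had no member analysed here, and 3 lists (auxin response with 8, calcium and touch with 6, wall loosening with 6) had the 5 members needed for a set test. Those were tested with limma's camera, with a preset inter-gene correlation of 0.01 and again with an estimated correlation, adjusted over the 3 lists of a comparison. Limma's fry was run beside it. Groups of at least 6 genes that share a symbol stem (48 families) were defined after the annotation was seen and before any value was tested. Lists of class III peroxidases and germin-like proteins were added after the largest changes were seen, and were adjusted over the pair.

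The text names PUCHI in every group. For each treatment comparison it draws on the 12 largest rises and 8 largest falls among called 1-gene probe sets whose 3 treated and 3 control arrays do not overlap. For interactions and genotype comparisons it draws on the 8 largest called values each way, and from a list with a call up to 4 members with the smallest p. Other genes are said to be chosen after their values were seen. Alternatives were a renewed quantile normalization, centring of arrays, an intensity trend with a robust prior, array weights, the replicate number as a block, a filter on dim probe sets, all rows of the table, a 2-fold minimum, fits of the compared arrays alone, and leaving out each array in turn. Leaving out the replicate 1 arrays of all groups was added after a principal component was seen to part them.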

Results

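TOLS2 is a small secreted peptide of the root, RLK7 is a receptor kinase, and PUCHI is an AP2/ERF transcription factor that acts in lateral root formation. The design asks which transcripts change within 3 h of 1 µM TOLS2 in root tips, and whether the change differs in the rlk7-3 mutant and in the mutant labelled puchi-2. Root tips of 5-day seedlings were measured on 18 arrays, 3 for each combination of genotype and treatment. Correlations between arrays were at least 0.983 over all rows, and at least 0.984 within a group. The first principal component held 21.1% of the variance and parted the TOLS2 arrays of wild type and puchi-2 from all other arrays, those of rlk7-3 with TOLS2 included. The next held 12.5% and set the replicate 1 arrays apart from the others of their group.

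PUCHI (AT5G18560) is both a response gene and the gene named in a genotype label. Its level was 4.56 ± 0.37 in wild-type control and 6.52 ± 0.07 with TOLS2 (log2, SD, n = 3). On rlk7-3 arrays it was 4.27 ± 0.10 and 4.43 ± 0.15. On arrays labelled puchi-2 it was 5.31 ± 0.23 in control and 6.25 ± 0.09 with TOLS2, so the signal was not lower than in wild type among controls, whereas with TOLS2 each of these arrays lay below each wild-type array. Neither the difference of 0.75 between the controls (limma adjusted p = 0.232) nor that of −0.27 between the TOLS2 arrays (adjusted p = 0.66) was called. The labels give neither the lesion nor the part of the transcript that the probes read, so this signal does not check the genotype, and the arrays are called puchi-2-labelled in what follows. The RLK7 transcript could not be followed, as no row was named for it.

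**Figure D1:**
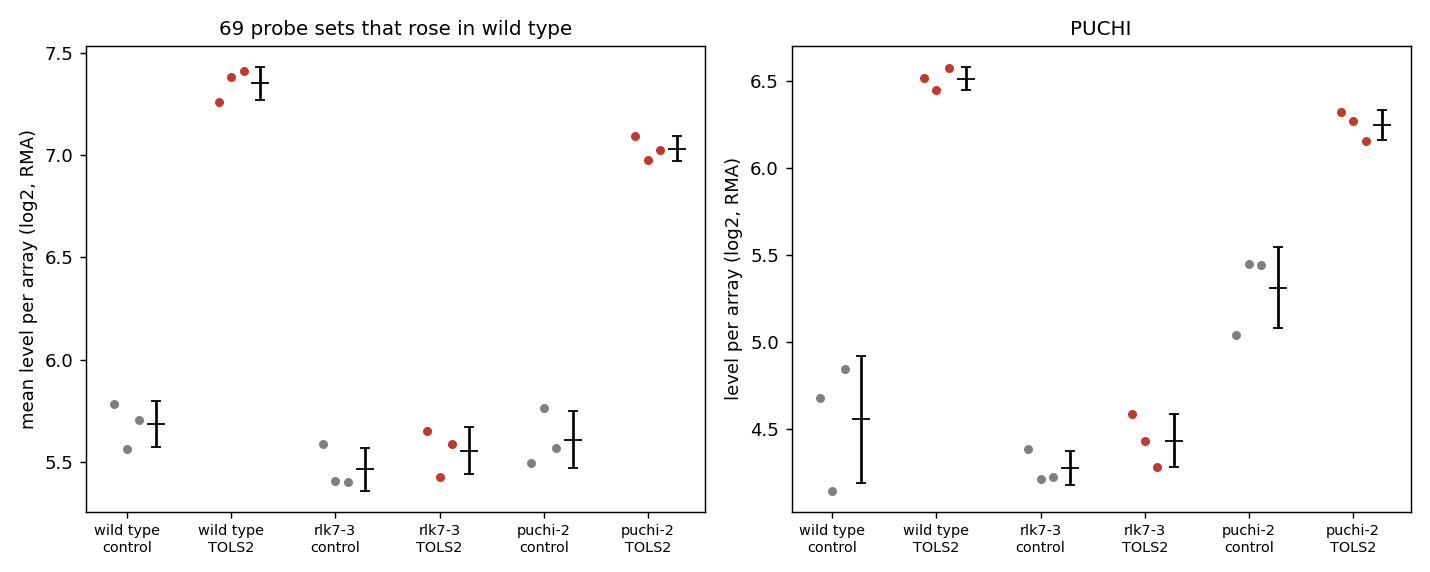
Each point is an array (3 per group), grey for control and red for TOLS2, and the bars give the group mean ± SD. Left, mean level (log2, RMA) of the 69 probe sets that rose at least 2-fold in wild type, which lay at 5.56 ± 0.12 in rlk7-3 with TOLS2 beside 7.35 ± 0.08 in wild type with TOLS2; right, PUCHI level (log2, RMA), which rose by 1.96 in wild type and by 0.94 on puchi-2-labelled arrays.

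In wild type, the largest rises with TOLS2 included peroxidase, chitinase-family, defensin and germin-like genes. AT2G43620, a chitinase family gene, rose 22.4-fold, from 3.53 ± 0.26 to 8.02 ± 0.23 (log2 change 4.48, SE 0.21, n = 3, adjusted p = 3.07e-08). The class III peroxidase gene PRX52 rose 17.3-fold, from 4.72 ± 0.15 to 8.83 ± 0.27. The peroxidase genes AT4G08780 and AT4G36430 rose by 2.64 and 2.57 on the log2 scale, the plant defensin gene PDF1.4 by 2.93, the germin-like gene AT5G39120 by 3.03 and the AP2/ERF gene AT5G61890 by 2.23. AT1G65500 rose by 4.24, AT3G57460 by 2.46, AT1G21520 by 2.45 and AT5G22530 by 2.06. The largest falls were smaller: GH9B17, a glycosyl hydrolase of the endoglucanase family, fell by 1.24, AT4G00165 by 1.21, AT5G62420 by 1.16, AT3G45080 by 1.12, AT1G49715 by 1.1, AT5G19970 by 1.03, AT5G41280 by 1.01 and AT3G45160 by 1.01. In all, limma called 321 of 17481 probe sets, 201 higher and 120 lower, of which 69 rose and 10 fell at least 2-fold. At an unadjusted p under 0.05 there were 2088, and in 18.7% of probe sets the treated and control arrays did not overlap, where chance gives 10%. The count was 187 without control replicate 2, 201 without control replicate 3, 185 without TOLS2 replicate 2, 179 without TOLS2 replicate 3 and 174 from the 6 wild-type arrays alone, and rose to 576 with array weights and 526 over all rows of the table. The call of AT5G39120 ended without any 1 of the wild-type arrays except TOLS2 replicate 1 (adjusted p from 0.0612 to 0.128), that of AT1G49715 without control replicate 1 or 2 or TOLS2 replicate 1 or 3 (0.0665 to 0.106), and that of AT3G45160 without control replicate 1 or 3 or TOLS2 replicate 1 (0.0546 to 0.0704). Without the replicate 1 arrays of all groups AT5G62420 (0.0593) and AT5G41280 (0.144) were not called either.

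Lateral root genes were among the wild-type rises. PUCHI rose 3.89-fold (log2 change 1.96, SE 0.15, n = 3, adjusted p = 3.63e-06) and LBD16, a LOB-domain transcription factor of lateral root initiation, rose from 8.18 ± 0.08 to 9.30 ± 0.08 (1.12, SE 0.09, adjusted p = 2.9e-06). Of the 4 lateral root genes measured these 2 rose, while LBD29 (−0.41) and the receptor kinase gene CR4 (−0.33) were not called; adjusted over the list alone, 2 were higher and 1 lower. In the auxin response list, LBD16 rose and GH3.1, of the auxin-inducible GH3 family, fell by 0.76 among 8 members; adjusted over the list alone, 1 was higher and 3 lower, and camera found no shift of the list (adjusted p = 0.823). The call of GH3.1 ended without any 1 wild-type array except TOLS2 replicate 1 (adjusted p from 0.0942 to 0.181). The calcium and touch list, all of calmodulin-like genes, had 0 of 6 members called by limma and 0 adjusted over the list alone; its median was −0.05 and its mean −0.04, while camera gave the direction as up (adjusted p = 0.823).

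Wall genes moved both ways in wild type. Among 6 wall-loosening genes, the xyloglucan endotransglucosylase gene XTH20 rose by 2.28 and the expansin gene EXPA4 by 0.59, XTH19 fell by 0.41, and EXPA7 (0.07), EXPA18 (0.09) and XTH18 (−0.03) were not called; adjusted over the list alone the counts were also 2 higher and 1 lower. Camera called the list as higher (median 0.08, mean 0.43, adjusted p = 0.0316), but not with the correlation estimated (adjusted p = 0.438 with an estimated correlation). XTH19 was not called without any 1 wild-type array except TOLS2 replicate 1 (adjusted p from 0.124 to 0.198), nor over all rows of the table (0.0644) or after centring of the arrays. Of 64 class III peroxidases, a list added after the largest changes were seen, 8 rose and 2 fell; adjusted over the list alone, 13 were higher and 3 lower. AT2G18150 rose by 1.71 and Prx37 by 0.80, whereas AT5G15180 fell by 0.96. The median of the list was −0.01 and its mean 0.21, and camera called it as higher (adjusted p = 0.00024, and adjusted p = 0.047 with an estimated correlation). As the largest changes prompted this list, the 4 peroxidases among them were left out in turn. Camera then gave p = 0.0492 for the other 60, and p = 0.262 with an estimated correlation. Of 19 germin-like genes, added in the same way, AT5G39120 and AT5G38940 rose; adjusted over the list alone, 4 were higher and 0 lower (adjusted p = 0.00246, and adjusted p = 0.047 with an estimated correlation). As AT5G39120 prompted this list, it was left out in turn, and camera then gave p = 0.0135 for the other 18, and p = 0.0809 with an estimated correlation.

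Other fixed lists held few measured genes and little change in wild type. None of the 4 immune genes (WRKY22, WRKY29, STZ and BIK1) was called, nor any of 4 abscisic acid, cold and drought genes, 2 cell cycle, 2 cytokinin, 2 iron and 2 root hair genes, nor the only measured genes of the jasmonate, xylem, stem cell niche, heat and peptide and receptor lists. Their counts were 0 also when adjusted over the list alone. Changes of the cell cycle genes AUR1 and AUR2 were 0.00 and −0.14. RCA, which encodes rubisco activase and was the only measured photosynthesis gene, fell by 0.65 (adjusted p = 0.0355; adjusted over the list alone, 1 lower). This call ended without any 1 of the 6 wild-type arrays (adjusted p from 0.0531 to 0.162).

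In rlk7-3, the wild-type response was largely not seen. AT2G43620 changed by 0.03, AT1G65500 by −0.03 and PRX52 by 0.29, and none of the 12 largest wild-type rises was called in rlk7-3, where their changes ran from −0.80 to 0.51. PUCHI changed by 0.16 (adjusted p = 0.856) and LBD16 by 0.05 (adjusted p = 0.938). The call was GSTU25 alone, a tau-class glutathione S-transferase gene, which rose by 0.83 (SE 0.11, n = 3, adjusted p = 0.0493), where it had risen by 1.79 in wild type. Limma called this 1 probe set, against 1255 at an unadjusted p under 0.05, and 12.2% of probe sets did not overlap, where chance gives 10%. GSTU25 was not called without any 1 of the 6 rlk7-3 arrays except TOLS2 replicate 3 (adjusted p from 0.0726 to 0.122), nor after a renewed quantile normalization or centring of the arrays (0 probe sets each). Without TOLS2 replicate 3 limma called 4 probe sets, without TOLS2 replicate 1 it called 2 others and without any other rlk7-3 array 0. With the replicate number as a block it called 16, 11 higher and 5 lower. Counts were 11 with an intensity trend and robust prior, 10 among the brighter probe sets, 7 over all rows and 4 with array weights.

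As a group, the 69 probe sets that rose at least 2-fold in wild type stayed near their control level in rlk7-3. Their mean per array was 5.46 ± 0.11 in control and 5.56 ± 0.12 with TOLS2, a change of 0.09 (exact permutation test, two-sided, p = 0.2, n = 3), beside 1.67 in wild type, where the sets were chosen. Each TOLS2 array lay above the control array of its replicate number (5.65, 5.43 and 5.59 against 5.59, 5.40 and 5.40), an order that the unpaired test does not use. The change was 0.06 after a renewed quantile normalization and 0.05 after centring of the arrays. The 10 probe sets that fell at least 2-fold in wild type changed by −0.18 in rlk7-3 (exact permutation p = 0.1, the smallest possible with n = 3) and by −1.14 in wild type. This rests on AT5G41280: the other 9, a choice made after its value was seen, changed by −0.09 in rlk7-3 (exact permutation p = 0.4). Of the 201 wild-type rises, 152 (75.6%) were also higher in rlk7-3, with a median change of 0.11. Of the 120 falls, 63 (52.5%) were lower. The median change of all tested probe sets in rlk7-3 was 0.06, a general shift upward with TOLS2. Part of the larger share among rises than among falls may come from this shift. At an unadjusted limma p under 0.05, 53 of the 321 moved in rlk7-3 with the wild-type sign and 7 against it, a count made after the values were seen. The highest of the other assignments of the rlk7-3 arrays gave 33 with the sign. The auxin response list had 0 of 8 genes called in rlk7-3 by limma and 1 lower adjusted over the list alone, and camera called it as lower (median −0.09, adjusted p = 0.011), but not with the correlation estimated (adjusted p = 0.0824 with an estimated correlation). The calcium and touch list had 0 of 6 called and 0 adjusted over the list alone, and was called as lower by camera in the same way (median −0.12, adjusted p = 0.0356, and adjusted p = 0.0824 with an estimated correlation). Wall-loosening genes were not shifted (0 called, 0 adjusted over the list alone, adjusted p = 0.806), nor were the 64 peroxidases (0 called, 0 adjusted over the list alone, adjusted p = 0.98) or the 4 lateral root genes (0 called, 0 adjusted over the list alone). Of both called lists, 1 stayed called after quantile normalization or centring.

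The difference between the rlk7-3 and wild-type responses was tested directly. It was −4.45 for AT2G43620, −4.27 for AT1G65500, −3.82 for PRX52, −2.85 for AT4G08780, −2.63 for PDF1.4, −2.48 for AT3G57460, −2.45 for AT5G61890 and −2.40 for AT4G36430, all called. PUCHI differed by −1.80 (adjusted p = 0.00083) and LBD16 by −1.08 (adjusted p = 0.000425), so 2 of the 4 lateral root genes were called; adjusted over the list alone, also 2 lower. GSTU25 differed by −0.97 (adjusted p = 0.013), whereas the differences of AT5G39120 (−3.83, adjusted p = 0.121) and XTH20 (−1.77, adjusted p = 0.243) were not called. The 8 genes named for the largest positive differences were AT5G19970 (1.2), AT3G45080 (1.09), the bZIP gene bZIP58 (1.03), AT4G10540 (1.01), AT2G18480 (0.94), AT5G54990 (0.87), AT2G36690 (0.83) and AT4G18970 (0.81). These 8 had lower values with TOLS2 in wild type, called for all but AT2G18480 (−0.54, adjusted p = 0.0528). For all of them but AT3G45080 and AT2G36690, part of the difference lay in higher mean values in rlk7-3, none of them called. This part was largest for AT2G18480 (0.40) and AT4G10540 (0.34). Limma called 67 probe sets, 48 lower and 19 higher, and 1828 at an unadjusted p under 0.05. The median difference of all tested probe sets was 0.09, a general shift upward. After a renewed quantile normalization 9 were called higher, and after centring of the arrays 14. Of these 67, 48 had risen and 14 had fallen in wild type, an overlap that comes in part from the wild-type arrays used in both tests. The other 5, all with a positive difference, were not called in wild type.

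Among peroxidases, 6 of 64 had a smaller and 1 a larger response in rlk7-3 (adjusted over the list alone, 7 and 1). The median of this list was 0.06, its mean −0.16, and camera called it as lower (adjusted p = 0.000142, and adjusted p = 0.062 with an estimated correlation). The list was prompted by wild-type rises, and the same wild-type arrays enter this difference, so a lower value was partly given in advance. The peroxidases that prompted the list were not left out for this comparison. Wall-loosening genes had 0 called and 2 lower adjusted over the list alone (median 0.01, mean −0.29, adjusted p = 0.086). For auxin response genes the count was 1 lower, LBD16, also adjusted over the list alone; their median was 0.12 and mean −0.02, and camera gave the direction as lower (adjusted p = 0.099). In the calcium and touch list 0 genes were called, 0 adjusted over the list alone (adjusted p = 0.116). The count of 67 fell to 37 without wild-type TOLS2 replicate 2, 40 without TOLS2 replicate 3, 43 and 42 without wild-type control replicates 2 and 3, 42 without either rlk7-3 control replicate 1 or 2, and 28 without the replicate 1 arrays of all groups, and was 101 with array weights. Without the replicate 1 arrays PUCHI (adjusted p = 0.0504), AT4G08780 (0.122), AT3G57460 (0.173) and AT5G19970 (0.0598) were not called, and the calls of PDF1.4, AT5G61890, AT3G45080, AT4G10540, AT2G18480, AT5G54990, AT2G36690 and AT4G18970 each ended without any 1 of at least 9 of the 12 arrays (adjusted p up to 0.135). Those of AT3G45080, AT4G10540, AT2G18480, AT5G54990, AT2G36690 and AT4G18970 also ended after a renewed quantile normalization (0.0577 to 0.0995).

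**Figure D2:**
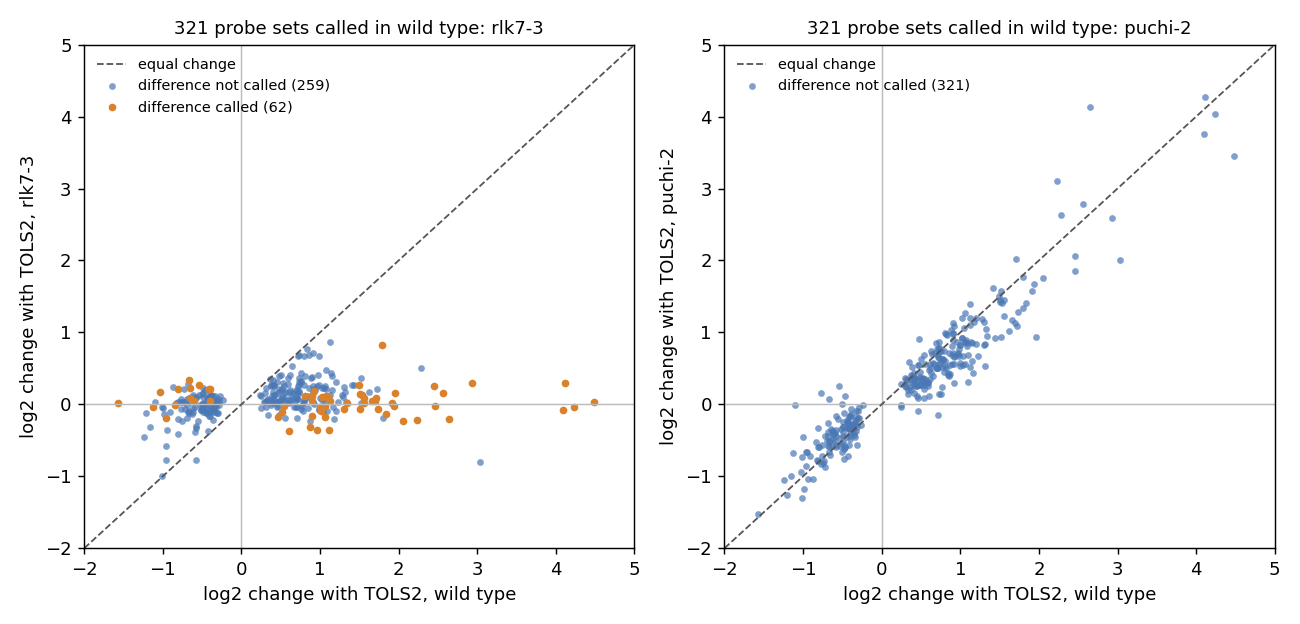
Each point is 1 of the 321 probe sets called in wild type, with its log2 change with TOLS2 in wild type (x axis) against that in rlk7-3 (left) or on puchi-2-labelled arrays (right), and the dashed line marks equal change. Orange points are the 62 whose change differed from wild type in the test of the difference, all in rlk7-3. The puchi-2-labelled points lie near the line (r = 0.949 across these probe sets, which are not independent replicates), and the limma test of the difference called 0 of them.

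On puchi-2-labelled arrays, TOLS2 raised largely the genes that rose in wild type. PRX52 rose by 4.27 (SE 0.22, n = 3, adjusted p = 9.43e-08), AT4G08780 by 4.13, AT1G65500 by 4.03, AT2G43620 by 3.45, AT5G61890 by 3.1, AT4G36430 by 2.78, XTH20 by 2.63, PDF1.4 by 2.59, AT3G57460 by 2.07, AT2G18150 by 2.01, AT1G21520 by 1.86 and GSTU25 by 1.77. AT4G08780 rose more than in wild type because its puchi-2-labelled control values were lower (5.40 to 6.01 against 7.22 to 7.45, not called). With TOLS2 its values overlapped (9.41 to 10.29 against 9.90 to 10.19 in wild type). Of the 12 largest wild-type rises, 11 were called here, and AT5G39120 (2.01, adjusted p = 0.163) was not. PUCHI rose by 0.94 (SE 0.15, adjusted p = 0.0047) and LBD16 by 0.52 (SE 0.09, adjusted p = 0.00498). Falls were led by the serine carboxypeptidase-like gene scpl22 (−1.36), AT3G45160 (−1.30), AT4G10860 (−1.28), AT4G00165 (−1.26), AT2G22122 (−1.17), the sugar transporter gene SWEET13 (−1.16), GH9B17 (−1.05) and AT4G39700 (−1.04). Limma called 279 probe sets, 157 higher and 122 lower, of which 46 rose and 10 fell at least 2-fold; 2215 had an unadjusted p under 0.05, and 17.2% did not overlap, where chance gives 10%. The count was 131, 183 and 159 without control replicates 1, 2 and 3, 114 without the replicate 1 arrays of all groups and 39 from the 6 arrays alone. It was 448 with an intensity trend or among the brighter probe sets, 443 over all rows, 487 with the replicate number as a block and 556 with array weights. Leaving out 1 array ended the calls of scpl22 (any but TOLS2 replicate 2), SWEET13 (any but TOLS2 replicate 1), AT4G10860 (control replicate 2 or 3, TOLS2 replicate 1 or 3), GH9B17 (control replicate 1 or 2) and AT4G39700 (control replicate 1), with adjusted p from 0.0515 to 0.172. Leaving out all replicate 1 arrays ended those of PUCHI (adjusted p = 0.14), LBD16 (0.0923) and AT3G45160 (0.0923).

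The same probe sets were called in both genotypes far more often than independent lists would share. Of the 201 wild-type rises 110 were called as rises on puchi-2-labelled arrays, where independent lists would share 1.81, and 197 (98.0%) had the same sign. Of the 120 falls 59 were shared, against 0.837, and 115 had the same sign. The changes themselves come from different arrays. The tests share an estimate of the spread per probe set over all arrays, so the lists are not fully independent and the numbers given for independent lists are too low. Across all probe sets, which are not independent replicates, the changes correlated with r = 0.573 (Spearman 0.350), and in rlk7-3 with r = 0.0934 (Spearman 0.0697). The 69 wild-type rises had a mean of 5.61 ± 0.14 in puchi-2-labelled control arrays and 7.03 ± 0.06 with TOLS2, a change of 1.42 (exact permutation p = 0.1, the smallest possible with n = 3). When the sets were chosen without 1 replicate number and wild type was measured in the number left out, the wild-type change was 1.67 and that of puchi-2-labelled arrays 1.52, or 90.8% as a ratio of these means. The 3 numbers left out gave 100.7%, 86.4% and 87.8% (SD 7.87). Each used all puchi-2-labelled arrays, so this SD does not measure the spread between them. The 46 probe sets that rose at least 2-fold on puchi-2-labelled arrays changed by 1.76 there and by 1.80 in wild type.

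Among probe sets with a gene, no difference between the responses of puchi-2-labelled and wild-type arrays was called. Limma called 0 of them, and 12 over all rows of the table, all rows of 1 pattern without a gene, with 708 of the 17481 at an unadjusted p under 0.05 and a lowest adjusted p of 0.709. LBD16 and PUCHI stood near the top of the ranking, at places 2 and 5 of 17481. The rise of LBD16 was smaller by −0.60 (95% interval −0.86 to −0.35) and that of PUCHI by −1.02 (95% interval −1.48 to −0.56), both with an adjusted p of 0.709. In the lateral root list these were 0 of 4 called, and 2 lower adjusted over the list alone. For PUCHI part of this lay in a higher signal on puchi-2-labelled control arrays (5.04 to 5.45, against 4.15 to 4.85 in wild-type control). LBD16 was lower on puchi-2-labelled arrays in control (7.83 to 7.89 against 8.09 to 8.25) and more so with TOLS2 (8.32 to 8.44 against 9.21 to 9.36). The median 95% interval of the difference reached 0.612 to either side over the 79 probe sets that changed at least 2-fold in wild type, so differences of the size seen for LBD16 were within the error for many of them, and 47 of the 79 intervals lay within ±1.

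Gene lists gave a similar picture on puchi-2-labelled arrays. In the wall-loosening list XTH20 rose and XTH19 fell by 0.57; adjusted over the list alone, 4 were higher and 1 lower, and camera called the list as higher (median 0.22, adjusted p = 0.0272, and adjusted p = 0.299 with an estimated correlation). The auxin response list held 1 rise, LBD16, and 4 lower adjusted over the list alone (1 higher), with adjusted p = 0.095. Its response was lower than in wild type by camera (0 called, 1 lower adjusted over the list alone, median −0.07, adjusted p = 0.028, and adjusted p = 0.244 with an estimated correlation). The 6 calcium and touch genes had 0 called and 0 adjusted over the list alone, both for the response (adjusted p = 0.280) and its difference from wild type (adjusted p = 0.300), and wall-loosening genes did not differ (0 called, 0 adjusted over the list alone, median 0.10 and mean 0.04 but direction lower, adjusted p = 0.882). Peroxidases had 7 rises and 1 fall (12 and 3 adjusted over the list alone, adjusted p = 0.000108, and adjusted p = 0.0577 with an estimated correlation). Lateral root genes had 2 rises, PUCHI and LBD16; adjusted over the list alone, 2 were higher and 1 lower.

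**Figure D3:**
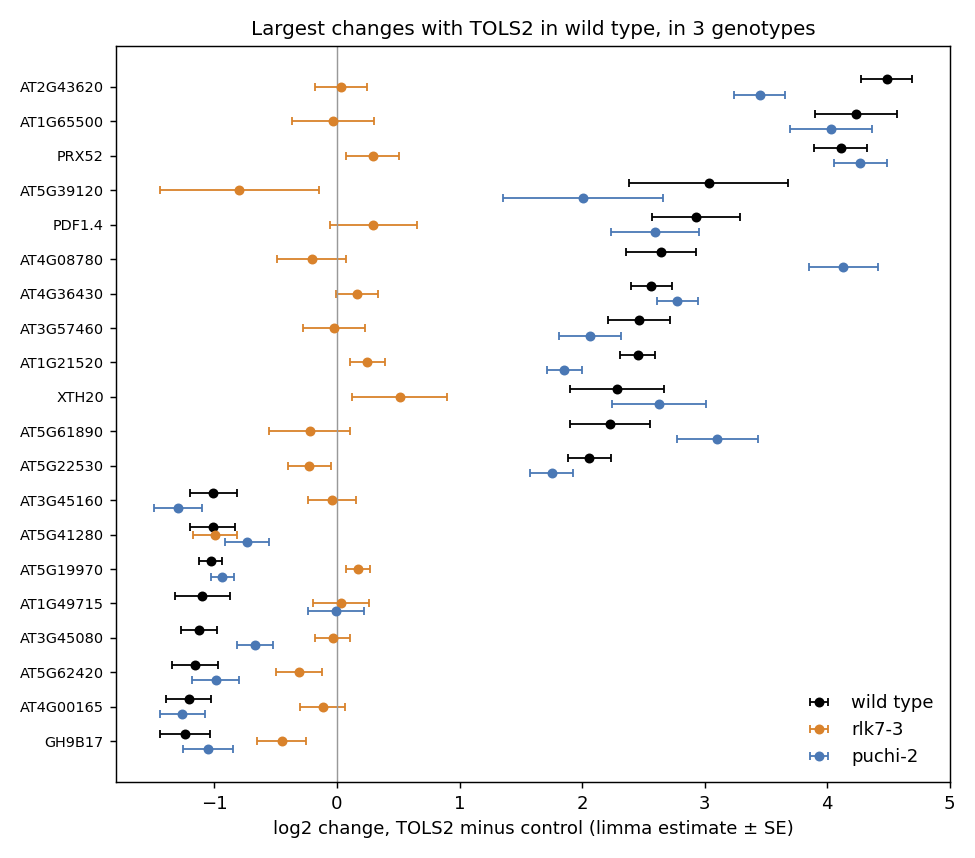
Log2 change with TOLS2 (limma estimate ± SE, x axis) of the 12 largest rises and 8 largest falls of wild type (y axis), in wild type (black), rlk7-3 (orange) and on puchi-2-labelled arrays (blue), with 3 arrays per group. AT2G43620 changed by 4.48, 0.03 and 3.45, and AT5G41280 by −1.01, −0.996 and −0.74, of which only the wild-type change was called.

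Without peptide, few transcripts differed between the mutants and wild type. In rlk7-3, ZCW7 was higher by 1.45 (6.31 ± 0.20 against 4.86 ± 0.17, n = 3, adjusted p = 0.000735), AT3G06435 by 0.93, AT5G52070 by 0.89 and AT1G34770 by 0.49, whereas AT1G27020 was lower (−1.24), as were AT1G53980 (−0.81), AT2G23400 (−0.65, adjusted p = 0.0293) and the cation exchanger gene CHX16 (−0.61). Limma called 9 probe sets, 4 higher and 5 lower, against 1293 at an unadjusted p under 0.05; 15.4% did not overlap, where chance gives 10%. The count was 19 with an intensity trend and robust prior, 18 with the replicate number as a block, 20 among the brighter probe sets and 15 over all rows. Leaving out any 1 of the 6 arrays left between 3 and 6 calls: 3, 4 and 3 without wild-type control replicates 1, 2 and 3, and 4, 6 and 4 without rlk7-3 control replicates 1, 2 and 3. The calls of AT1G34770, AT1G27020 and AT2G23400 ended without any 1 array (adjusted p from 0.0592 to 0.211), that of CHX16 without any but rlk7-3 control replicate 2 (0.086 to 0.211), and that of AT1G53980 without wild-type replicate 1 or 3 or rlk7-3 replicate 1 (0.0568 to 0.0679); only 1 call was made without the replicate 1 arrays of all groups, and ZCW7 and AT5G52070 were not called then (adjusted p = 0.119 each).

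On puchi-2-labelled control arrays, QQS, a gene of starch metabolism found in Arabidopsis thaliana alone, was higher by 2.86 (7.11 ± 0.26 against 4.25 ± 0.28, n = 3, adjusted p = 7.51e-06), ZCW7 was higher by 1.38 (adjusted p = 0.00215) and AT2G23400 lower (−0.75, adjusted p = 0.0106). These were the 3 calls of limma, with 1092 at an unadjusted p under 0.05, and 13.2% without overlap, where chance gives 10%. AT2G23400 was not called without wild-type control replicate 1 or 2 or puchi-2-labelled replicate 2 or 3 (adjusted p from 0.0563 to 0.112), and ZCW7 not without the replicate 1 arrays of all groups (adjusted p = 0.368). ZCW7 and AT2G23400 were called with the same sign in both mutants, which share the wild-type control arrays. Unchanged groups simulated against those arrays shared 0 calls on average (largest 0 of 100 simulations), and independent lists would share 0.000458 higher and 0.000286 lower. The differences of both mutants correlated with r = 0.547 across probe sets, where the simulated value is 0.500, and had a covariance of 0.0162 against a simulated 0.0119, so most of this correlation is what the shared controls alone give.

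Of the tested lists, auxin response genes were higher on puchi-2-labelled control arrays by camera (0 of 8 called by limma, 2 higher and 1 lower adjusted over the list alone, median 0.31, adjusted p = 0.0106), a call that was not kept with the correlation estimated (adjusted p = 0.162 with an estimated correlation). In that genotype the calcium and touch and wall-loosening lists were not shifted (0 called and 0 adjusted over the list alone in each, adjusted p = 0.239 for both). In rlk7-3 controls the auxin response, calcium and touch and wall-loosening lists were not shifted either (0 called and 0 adjusted over the list alone in each, adjusted p = 0.662 for each). Of 4 lateral root genes, 0 were called in either mutant; adjusted over the list alone, PUCHI was higher and LBD16 lower on puchi-2-labelled arrays.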

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

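The tests of the spread between rlk7-3 arrays, of peptide delivery and treatment of the rlk7-3 arrays, of a general shift of the puchi-2-labelled arrays and of their identity with wild type were chosen only after the results were seen, as were the share of calls on the RLK7 chromosome, the genotype differences among TOLS2 arrays, the choice of probe sets without 1 replicate number and the breakdown of splits by wild-type group.

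The response to TOLS2 differed between genotypes in the direct test: 67 probe sets responded otherwise in rlk7-3 than in wild type, and the response of PUCHI differed by −1.80. A larger spread between the rlk7-3 arrays would hide changes but leave their mean size, and this is argued against, since the mean change of the wild-type rises, chosen without 1 replicate number, was 5.12% of that in the left-out wild-type arrays. Whether the rlk7-3 arrays labelled TOLS2 were treated was examined through changes shared with wild type, which can show a difference from the rlk7-3 controls but not its source. Of the 100 rows of the table with the smallest p in rlk7-3, 23 were called in wild type with the same sign and 1 with the opposite one. Without any 1 rlk7-3 array, 15 to 28 had the same sign and 1 to 6 the opposite one. The highest of the 19 other assignments of these arrays gave 7 with the same sign. With 20 assignments a share under 0.05 cannot be reached, so untreated arrays are not excluded. This list of fixed length replaced a bound on the calls alone, which fits with 1 call could not meet. Peptide that did not reach these arrays, or reached them at a lower dose, cannot be told apart from a missing response of most genes: the wild-type rises changed by 0.0905, and the shared changes argue for delivery only if they come from the peptide and not from another difference between the media, which the design does not measure. That the rlk7-3 mutation removes most of the response is the biological explanation and stays a hypothesis.

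The split of the arrays was compared with other splits into groups of the same sizes. For wild type 1 of 10 splits, the real one, called as many probe sets (321, highest other 0), for rlk7-3 2 of 10 (1, highest other 1), for puchi-2-labelled arrays 1 of 10 (279, highest other 1), for rlk7-3 controls 1 of 10 (9, highest other 0) and for puchi-2-labelled controls 1 of 10 (3, highest other 0). With 10 splits a share under 0.05 cannot be reached. For the rlk7-3 difference 9 of 100 splits called as many as the real 67 (highest other 119), so chance is not excluded by this count. The 8 others all keep the wild-type groups as they are and mix only the rlk7-3 arrays, and the highest split that parts the wild-type groups called 2, so the count rests on the wild-type response. For the puchi-2 difference the real count is 0 by limma (708 at an unadjusted p under 0.05), so 100 of 100 splits reach it; the highest other, 933, swaps the puchi-2 treatment labels and points to a structure of the samples, the shared response.

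The signal of PUCHI was not lower on puchi-2-labelled control arrays, whereas with TOLS2 each of these arrays lay below each wild-type array (6.25 ± 0.09 against 6.52 ± 0.07, limma adjusted p = 0.66). A general shift of these control arrays is argued against, since the difference of PUCHI lay at percentile 99.95 of all tested probe sets. That these samples came from the same plants or stock as the wild-type samples is argued against too: 7 rows of the table differed between puchi-2-labelled and wild-type control arrays and again, with the same sign, in the TOLS2 arrays. ZCW7 and AT2G23400 also differed in this way in rlk7-3. Other inherited differences between seed stocks would give such rows as well, so they cannot show that PUCHI is mutated. A transcript that is still made and read by the probes may remain, but neither the lesion nor the probe position is given in the labels, and no biological explanation was tested.

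ZCW7 and AT2G23400 differed from wild type in the controls of both mutants. A chance deviation of the 3 shared wild-type control arrays is argued against, since all 4 of these differences were called with the same sign among the TOLS2 arrays, which are other arrays. A linked background around the mutated locus would place the rlk7-3 calls near RLK7. Of the 8 calls with a named gene, 0 lay within 500 genes of it, the nearest 1726 genes away. Of these 8, 5 were on its chromosome, where 26.0% of tested genes lie (exact hypergeometric test, one-sided, p = 0.0322). With every row tested, 8 of the 15 calls were rows without an annotated gene, the largest fall among them being −2.35 in row 13338174. Such rows were not placed on the chromosomes, so this test cannot decide whether calls lie near RLK7. Other inherited differences between the seed stocks may remain, and the design holds no second line of either mutant to test this.

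Rows of the table without an annotated gene were outside the comparisons, and 255 of them were called with TOLS2 in wild type. The largest rise in wild type among them was 5.04 in row 13452792, which also rose by 4.54 on puchi-2-labelled arrays and changed by 0.17 in rlk7-3. The largest fall in wild type among them was −2.47 in row 13448275 (limma adjusted p = 0.0107). This row changed by −2.52 in rlk7-3 (adjusted p = 0.101) and by −1.13 on puchi-2-labelled arrays (adjusted p = 0.330). Its rlk7-3 response differed from that of wild type by −0.05 (adjusted p = 0.990). In rlk7-3 controls the largest fall was −2.35 in row 13338174 and the largest rise 1.72 in row 13390441. On puchi-2-labelled controls the largest fall was −3.26 in row 13495420. With all rows tested, the puchi-2 difference had 12 calls, all of them rows with identical values and so 1 pattern.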

How the results depend on the processing

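Leaving out all replicate 1 arrays was chosen after the results were seen; the other settings were fixed beforehand. Counts of called probe sets are given where they moved by more than 1.5 times. For wild type (321) they were 576 with array weights, 526 over every row, 79 at 2-fold and 174 from only the arrays compared. For rlk7-3 (1) they were 0 after quantile normalization, 0 after centring, 0 at 2-fold, 0 without the replicate 1 arrays, 0 from only the arrays compared, 11 with an intensity trend, 4 with array weights, 16 with the replicate block, 10 above the median level and 7 over every row. For puchi-2-labelled arrays (279) they were 448 with a trend, 556 with weights, 487 with the block, 448 above the median level, 443 over every row, 56 at 2-fold, 114 without replicate 1 and 39 from only the arrays compared. For the rlk7-3 difference (67) they were 101 with weights, 41 at 2-fold and 28 without replicate 1, and for the puchi-2 difference (0; 708 at an unadjusted p under 0.05 by limma) 12 over every row. For rlk7-3 controls (9) they were 19 with a trend, 18 with the block, 20 above the median level, 15 over every row, 2 at 2-fold, 1 without replicate 1 and 2 from only the arrays compared. For puchi-2-labelled controls (3) they were 1 above the median level, 8 over every row, 1 without replicate 1 and 1 from only the arrays compared.

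Without single arrays the counts ran from 179 to 308 (wild type), 0 to 4 (rlk7-3), 131 to 208 (puchi-2-labelled), 37 to 56 (rlk7-3 difference), 0 to 0 (puchi-2 difference), 3 to 6 (rlk7-3 controls) and 2 to 3 (puchi-2-labelled controls). The mean change of the wild-type rises ran from 0.0433 to 0.155 in rlk7-3 and from 1.37 to 1.5 on puchi-2-labelled arrays, where it was 0.81 with no minimum change and 0.89 for the falls with the sign turned. Quantile normalization kept 309 of the 321 wild-type calls, centring 297, and array weights 320.

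Gene lists called by camera numbered 1 in wild type, 2 in rlk7-3, 1 in puchi-2-labelled arrays, 1 for the puchi-2 difference and 1 in puchi-2-labelled controls; each count was 0 with an estimated correlation and 0 with fry. In rlk7-3 it was 1 after quantile normalization and 1 after centring. With the block it was 0 in wild type, 0 in puchi-2-labelled arrays and 0 for the puchi-2 difference. The filter on dim probe sets was not run for lists, as fewer than 5 members were left.

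Of 78 calls of named genes, 52 were made without any 1 array and 36 in all settings as well, and 0 turned their sign. Replicate numbers were not taken to pair samples in the main fit, since only 6 of 15 pairs of groups and numbers correlated above 0.1 (r from −0.0667 to 0.267). Yet 11 of the 15 correlated best with their own number, which points to a batch shared by number. All pairs of number 1 had a positive r (lowest 0.0724), and the second principal component parted these arrays, so such a batch is not excluded. With the replicate block limma called 476 probe sets in wild type, 16 in rlk7-3 and 487 on puchi-2-labelled arrays.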

Other observations

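The glucosyltransferase and glutathione S-transferase genes below, the peroxidase and germin-like lists and the stricter bound for peroxidases were chosen only after the results were seen. A few of these changed to a similar degree in wild type and rlk7-3, where the median difference over the 201 wild-type rises was −0.69 (48 called). The glucosyltransferase gene UGT73B5 rose in wild type by 0.74 (limma adjusted p = 0.00104, n = 3) and changed by 0.68 in rlk7-3 (adjusted p = 0.0554), and the glutathione S-transferase gene GSTU22 rose by 0.72 and changed by 0.67 (adjusted p = 0.0554). UGT73B4 changed by 0.91 and 0.72 (adjusted p = 0.284 in rlk7-3), and UGT73B3 by 0.64 and 0.53 (adjusted p = 0.256 in rlk7-3). The difference between genotypes was close to 0 for UGT73B5 (−0.05, adjusted p = 0.923), GSTU22 (−0.04, adjusted p = 0.939), UGT73B3 (−0.11, adjusted p = 0.865) and UGT73B4 (−0.19, adjusted p = 0.835), though not for UGT87A2, which rose by 1.14 in wild type and changed by 0.43 in rlk7-3 (difference −0.71, adjusted p = 0.134). GSTU25 also changed in rlk7-3 (0.83), but less than in wild type (1.79). On puchi-2-labelled arrays UGT73B5 rose by 0.57, GSTU22 by 0.69, UGT73B4 by 0.89 and UGT73B3 by 0.70. Apart from GSTU25, none of these was called in rlk7-3.

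Gene families were grouped by shared symbol stems after the annotation was seen. Of 48 families, camera called 7 in wild type: ATL, BGLU, PDF, PUB and UGT as higher and GH and TBL as lower. None of these calls was kept with the correlation estimated (adjusted p = 0.341 with an estimated correlation for ATL and 0.345 for the others). Among 51 UGT genes, 4 rose and 0 fell (8 and 0 adjusted over the list alone, adjusted p = 0.0198, and adjusted p = 0.345 with an estimated correlation). Of 23 TBL genes, TBL33 and TBL19 fell by 0.34 and 0.40 (4 lower adjusted over the list alone, adjusted p = 0.0198, and adjusted p = 0.345 with an estimated correlation). In rlk7-3 camera called 0 families, on puchi-2-labelled arrays 1 (TBL), and for the rlk7-3 difference 3 (ATL, BGLU and PUB). With the correlation estimated 0 were called in any comparison.

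Without peptide, no peroxidase was called as different in either mutant. Camera called the 64 class III peroxidases as lower at the preset correlation alone, in rlk7-3 controls (0 called by limma, 1 lower adjusted over the list alone, median −0.08, adjusted p = 0.00274, and adjusted p = 0.145 with an estimated correlation) and in puchi-2-labelled controls (0 called, 2 lower adjusted over the list alone, median −0.07, adjusted p = 0.000545, and adjusted p = 0.0899 with an estimated correlation). The mutants share the wild-type controls, so these are not independent. For the 19 germin-like genes, camera gave a smaller response in rlk7-3 at the preset correlation alone (0 called by limma, 1 lower adjusted over the list alone, median 0.10, mean −0.30, adjusted p = 0.0128, and adjusted p = 0.094 with an estimated correlation). Without AT5G39120, which prompted the list, that call of camera was not kept, with the preset correlation or an estimated one.

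The rise of the peroxidase list in wild type may come from few genes rather than the family. Without the 4 peroxidases among the largest changes, 60 were left, of which 4 rose and 2 fell, and camera gave p = 0.0492 from limma's preset correlation. The bound written before this value was seen was a p under 0.05, which this value meets barely and which would have argued against few genes as the cause. With an estimated correlation p is 0.262, and the median of the 60 is −0.04, which go the other way. The bound was made stricter after the value was seen, to need both p values under 0.05, because the preset correlation of 0.01 is smaller than that among these genes, so whether the family or few genes moved stays open.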
